A study of Homo sapiens with 2 samples.

How the data were processed

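Single-cell RNA counts were analysed for 2 libraries of blastoids made from H1 cells kept in PXGL medium. The deposited values are UMI counts per gene and cell barcode, not normalized, for 36601 features, and were made with Cell Ranger 7.1.0, per the file headers. The genome was hg38, per the submitters' processing notes. The gene annotation release and whether the 3' or the 5' end of transcripts was read were not given in the sources used here. Groups were taken from the genotype labels, with 1 library labelled shControl and 1 labelled shH2AJ. Gene coordinates are those of GENCODE 29 on the same genome build.

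Barcodes were kept with at least 1000 UMIs, at least 500 genes and at most 20% mitochondrial UMIs. Doublets were scored against simulated ones, and the highest scores were removed at 0.8% per 1000 barcodes, which took 175 of 4023 and 349 of 6232 passing cells. The number removed is set by that rate, so it does not measure how many doublets were present. The kept cells held 79039790 and 65890561 UMIs, with a median of 4924 and 3656 genes and of 4.83% and 5.79% mitochondrial UMIs per cell. Both libraries were clustered together with the Leiden method at resolution 0.5, on 15 neighbours in 30 principal components of 2000 variable genes.

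Clusters were named from 12 marker lists with 138 genes, fixed before the data were examined, as were 21 other gene lists, the rules for naming genes, the filters and most alternative settings. A cluster took the name of its best list where the mean log2 level of that list over the other cells was at least 0.5 and at least 3 markers at 10 CPM or more were 1.5-fold higher. These thresholds were chosen after the data were seen, as was joining clusters with naive and primed epiblast markers into the epiblast-like class. The union of trophoblast lists was fixed before. The log2 levels used a pseudocount of 1 CPM. A cluster stayed unnamed where it held fewer than 20 cells, where its UMIs per cell were low and no marker led it, or where more markers of another class than of its own stood among its top 10 genes.

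UMI counts were summed per library over all kept cells and over each class with at least 100 cells in both libraries, then scaled to the same total per library (CPM). With 1 library per genotype no test was made, since cells are not replicates. Levels carry exact Poisson intervals, shares exact binomial (Clopper-Pearson) intervals and ratios exact conditional intervals, all at 95% and for counting error only. The genes named are H2AFJ, then the 12 highest and 12 lowest log2 ratios among genes with at least 20 CPM in the higher library and at least 50 UMIs in all. From each list the rule takes up to 4 members at 10 CPM or more with the largest ratios, and any member opposite to the list's median. Mitochondrial and ribosomal protein genes, clone names, XIST, TSIX and Y-linked genes were left out of that ranking. List medians carry an order-statistic interval and a percentile among 10000 random lists matched on mean expression in 20 bins.

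RNA from other cells gives UMIs in cells that do not express a gene. The background was estimated from naive epiblast markers in trophoblast-like cells, whose median level was 14.1% and 12.0% of the whole-library level in the libraries labelled shControl and shH2AJ. Trophectoderm markers in epiblast-like cells stood at 10.3% and 14.9%. A gene was taken as being at the background level where the higher library lay at or below 1.5 times these medians, a rule chosen after the data were seen. The limit was set from these 2 lists, so it does not test whether their own members are expressed.

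The calculations were tested on simulated data with 200 genes of known fold. Counts were drawn with Poisson error from the pooled profile of both libraries, which is the error the intervals assume. Spread between cells, clustering and differences between libraries were not simulated. The values below therefore check the arithmetic only, and not the ratios of the real libraries. In each of the 3 comparisons, 100% of genes made 2-fold or 4-fold different were called by the 1.5-fold rule and 0% of those made 1.25-fold different. The intervals held the true value for 95.3% of 6588 unchanged genes over all cells, 95.1% of 6920 in epiblast-like cells and 95.5% of 5957 in trophoblast-like cells. Among the 66 or 67 genes at each known fold, coverage lay between 89.4% (4-fold, all cells) and 98.5%. Alternatives covered the cell filters, doublet removal, scaling, clustering, cell naming, depth per cell and class weights. Ratios of single genes were recomputed only under the cell filters, doublet removal and scaling. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9.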

Results

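Single-cell RNA counts were available for 2 libraries of human blastoids, which are stem-cell-derived models of the blastocyst. Both were made from H1, an established human embryonic stem cell line, kept in PXGL, a medium for the naive pluripotent state. The labels give 1 library the genotype shControl and the other shH2AJ, a short hairpin RNA against the histone variant gene H2AJ. The library labelled shControl held 5451 barcodes with 88111502 unique molecular identifiers (UMIs). The library labelled shH2AJ held 7005 barcodes with 73703866 UMIs. After filtering and doublet removal, 3848 and 5883 cells were kept, with a median of 18957.5 and 9598 UMIs per cell. There were no replicate libraries, so no difference below has a replicate check or a test. Intervals in square brackets are exact 95% intervals that cover counting error only, and they describe these libraries rather than the genotypes. A gene is called higher or lower where its level differed by at least 1.5-fold (log2 0.58), and log2 ratios are those of the library labelled shH2AJ over the library labelled shControl.

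The targeted gene was measured first. It is listed as H2AFJ (ENSG00000246705), an older symbol of H2AJ, and lies on chromosome 12 from 14774383 to 14778002 on the plus strand (hg38). H2AFJ was not lower in the library labelled shH2AJ. It stood at 31.7 CPM (UMIs of a gene, scaled to the same total in each library) [30.4, 32.9] from 2502 UMIs in the library labelled shControl. It stood at 31.6 CPM [30.3, 33.0] from 2082 UMIs in the library labelled shH2AJ, a log2 ratio of -0.003 [-0.087, 0.082]. Within epiblast-like cells the levels were 36.5 and 31.1 CPM, a log2 ratio of -0.23 [-0.36, -0.097]. Within trophoblast-like cells they were 29.9 and 33.5 CPM, a log2 ratio of 0.16 [0.028, 0.30]. In hypoblast-like cells H2AFJ had 3 UMIs against 32, too few to compare. The directions given below are therefore tied to the labels of the libraries, because the RNA level of the target did not separate them. H2A genes resemble each other in sequence, so reads that H2AFJ shares with other family members could not be told apart from these counts.

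**Figure D1:**
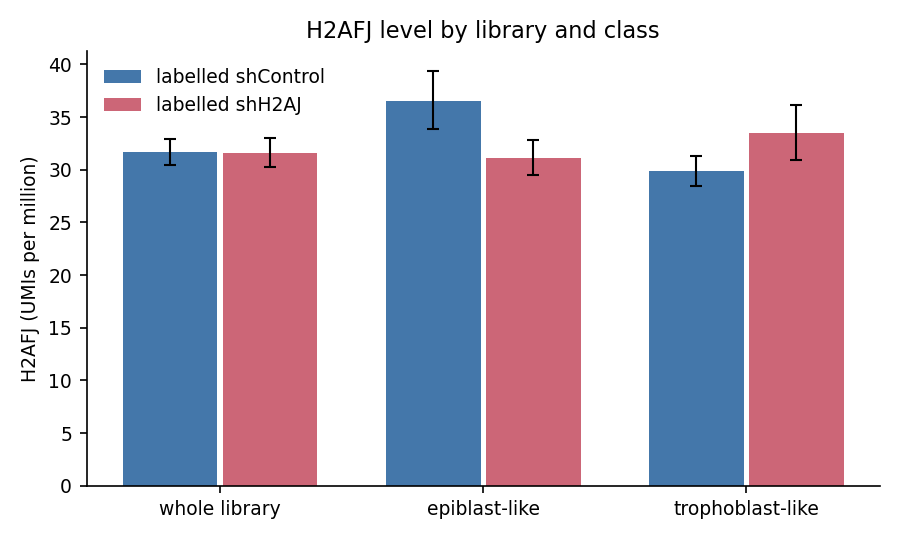
H2AFJ level in CPM (vertical axis) for all kept cells and for each main class, with 1 bar per library and exact 95% Poisson intervals as error bars. The bars for all kept cells stand at 31.7 and 31.6 CPM, and the order of the libraries is opposite in the 2 classes.

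The first comparison asked which embryonic lineages made up the blastoids of each label. Trophoblast-like cells, named from trophectoderm and later placental markers, made up 60.5% [58.9, 62.0] of kept cells (2328 of 3848) in the library labelled shControl. They made up 18.5% [17.6, 19.6] (1091 of 5883) in the library labelled shH2AJ, a 3.26-fold lower share [3.03, 3.51]. Epiblast-like cells, named from pluripotency markers, made up 28.1% [26.7, 29.6] (1083 cells) against 72.7% [71.5, 73.8] (4277 cells), a ratio of 2.58 [2.42, 2.76]. Hypoblast-like cells, with APOA1, SOX17, PDGFRA and FOXA2 among their leading genes, were 13 cells (0.338% [0.18, 0.577]) against 60 cells (1.02% [0.779, 1.31]). No cluster of kept cells was named amnion-like, mesoderm-like, mesenchyme-like or eight-cell-like, but with each library clustered alone 49 cells labelled shH2AJ (0.833%) were mesenchyme-like. Clusters 10 and 11 matched mesenchyme markers best, with 2 markers higher in each, but stayed unnamed. They held 1.66% and 0.799%, and 0.442% and 1.12%, of kept cells, and cluster 11 was led by interferon-induced genes. Cluster 8, named epiblast-like, had eight-cell markers at a mean log2 of 0.78 over other cells and held 0.052% and 3.98%. Without the cell filters, 0.459% and 1.24% of barcodes fell in amnion-like clusters and 3.94% and 2.77% in mesenchyme-like ones. Unnamed clusters held 11.02% and 7.73% of cells. Among them was a cluster with late trophectoderm markers below the naming threshold, which was set after the data were seen, with 2.37% and 0.799%.

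The shares kept their order when marker genes and H2AFJ were left out of clustering but not out of the naming, with 60.4% and 18.7% trophoblast-like cells. The libraries differed in depth. The filters and doublet removal together kept 70.6% of barcodes in the library labelled shControl against 84.0% in the library labelled shH2AJ. In these libraries 22.6% and 9.14% of barcodes exceeded 20% mitochondrial UMIs. At a finer clustering resolution of 1.0 the trophoblast-like share was 29.5% against 17.2%, a ratio of 0.584 in place of 0.307, and 45.0% of cells labelled shControl went unnamed. The hypoblast-like ratio of 3.02 [1.64, 5.995] was 14.4 under a strict cell filter, 1.02 with cells assigned by marker score and 0.243 with each library clustered alone.

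**Figure D2:**
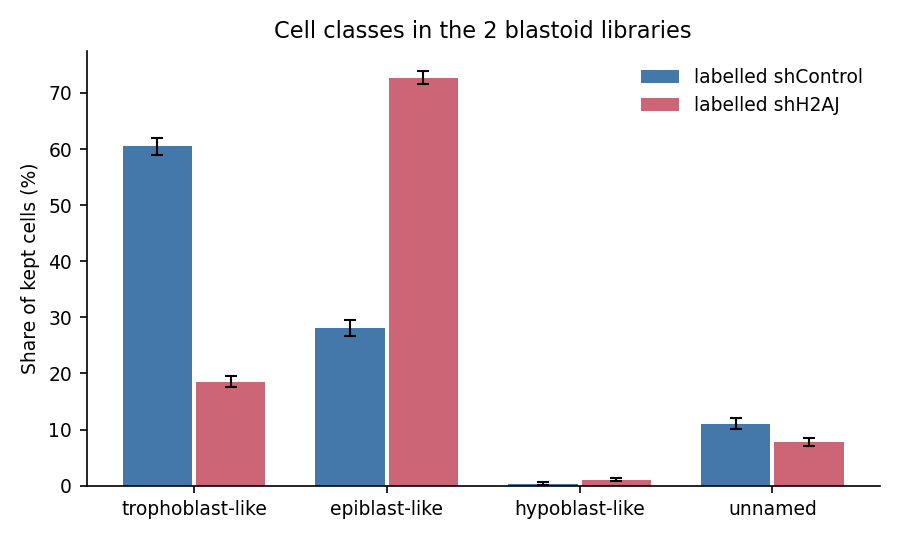
Share of kept cells in each class (vertical axis, percent), with 1 bar per library and exact 95% binomial intervals as error bars. Trophoblast-like cells are 60.5% and 18.5%, and epiblast-like cells 28.1% and 72.7%, in the libraries labelled shControl and shH2AJ.

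The second comparison took all kept cells of each library together. Markers of the trophectoderm, the outer layer that forms the placenta, were lower in the library labelled shH2AJ for 13 of 15 measured genes and higher for 0. GATA3, a transcription factor of the trophectoderm, stood at 90.2 CPM against 259 in the library labelled shControl, a log2 ratio of -1.52 [-1.56, -1.478]. KRT19, a keratin of simple epithelia, had a log2 ratio of -1.77, and CDX2, a homeobox factor of the early trophectoderm, -1.53. Naive epiblast markers were higher for 13 of 14 genes and lower for 0. NODAL, a signalling ligand of the epiblast, stood at 82.5 against 10.3 CPM (log2 ratio 2.999 [2.89, 3.11]), FGF4 had a log2 ratio of 1.90 and GDF3 1.84. The median log2 ratio was -1.23 [-1.52, -0.85] for the trophectoderm list and 1.39 [0.785, 1.84] for the naive epiblast list, at percentiles 0 and 100 among 10000 random lists matched on expression. CPM scaling left the median over genes at a log2 ratio of 0.13, and both medians lie far from that shift. With both libraries weighted to the same class shares, the medians were -0.008 and 0.08. The classes were named with these same lists, and unnamed cells were left out of the weighting. These medians are therefore not independent of the naming.

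Among single genes, the highest log2 ratios in all kept cells were those of SFRP2, a secreted WNT inhibitor (6.58 [6.12, 7.07]), THY1, a surface glycoprotein (5.46), and LEFTY1, an inhibitor of NODAL signalling (5.21). GRID2, a glutamate receptor subunit, stood at 1470 CPM against 104. The lowest were S100A6, a calcium-binding protein (-3.05), AQP3, a water channel (-2.90), ATP6V0D2, a proton pump subunit, and FOLR1, a folate receptor. All 7 measured metallothioneins, which bind metal ions, were higher, with a median log2 ratio of 1.253 [0.985, 2.29], or 0.42 with both libraries weighted to the same class shares. In epiblast-like cells 1 of 7 was higher, with a median of 0.23 [-0.30, 1.10]. There MT1G stood at 308% and MT1H at 327% of their whole-library level in the library labelled shControl. Targets of ERK signalling were higher for 5 of 7 genes and lower for 0, including ETV4 (2.03) and SPRY2 (1.62). Their median of 1.253 [-0.089, 2.03], an interval that includes 0, was 0.66 at the same class shares. Cholesterol synthesis genes were lower for 7 of 16 and higher for 1, including HMGCS1 (-1.44), which makes the HMG-CoA of that pathway. Their median was -0.51 [-0.998, 0.247], an interval that includes 0. Within epiblast-like cells 3 of the 16 were higher and 0 lower, and HMGCS1 had a log2 ratio of 0.038.

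**Figure D3:**
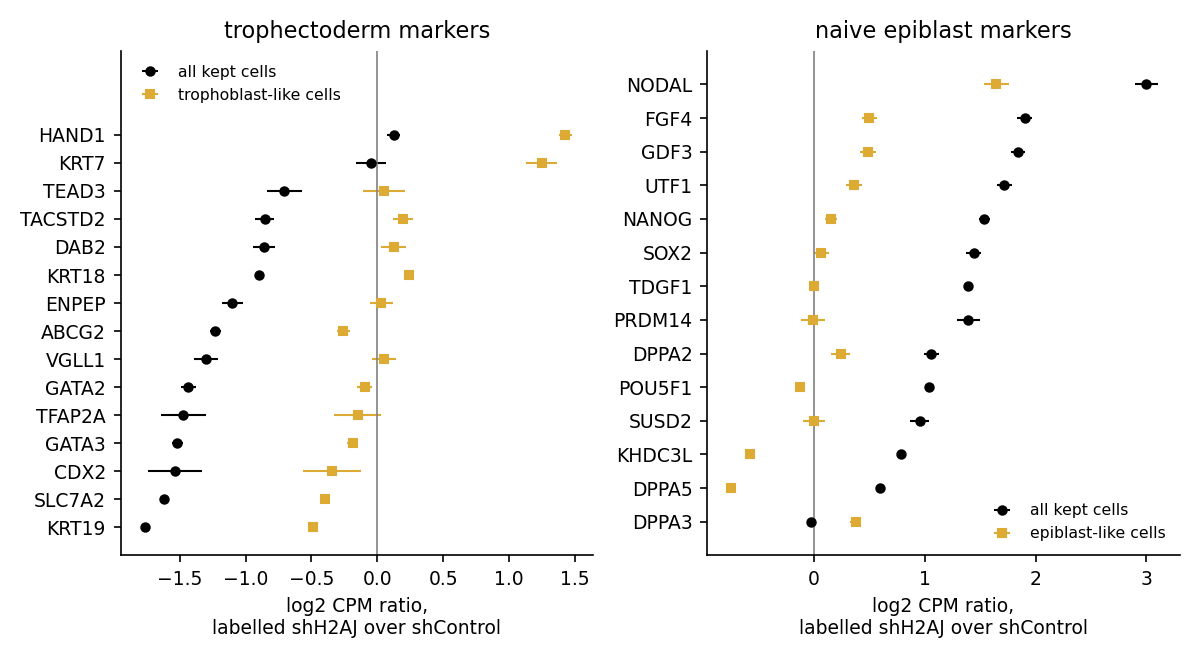
Log2 CPM ratio of the library labelled shH2AJ over the library labelled shControl (horizontal axis) for trophectoderm markers (left) and naive epiblast markers (right). Black circles are all kept cells, yellow squares are cells of the matching class, and lines are exact 95% counting intervals. Most ratios lie nearer to 0 within the class, while HAND1 and KRT7 stand at 1.43 and 1.248.

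The third comparison looked within epiblast-like cells, 1083 cells labelled shControl and 4277 labelled shH2AJ. The naive epiblast markers, which also named these clusters, stayed within 1.5-fold for 13 of 16 genes, with a median log2 ratio of 0.11 [-0.13, 0.49]. Of the 3 others, NODAL was higher (1.64), and ARGFX (-2.03), a homeobox gene of the early embryo, and DPPA5 (-0.75) were lower. KHDC3L lay just inside the limit at -0.579 [-0.62, -0.54]. Of 10 listed markers of primed epiblast, the later pluripotent state, 7 reached 10 CPM in the higher library. Among these 7, 5 were higher in the library labelled shH2AJ and 0 lower. ZIC3 (0.185) and SFRP1 (-0.27 [-0.45, -0.081]) stayed within 1.5-fold. SFRP2 stood at 66.96 CPM against 1.93 (5.12 [4.65, 5.63]), THY1 at 68.2 against 3.76 (4.18), CD24, a surface protein, at 311 against 71.7 (2.12), and PTPRZ1 had a log2 ratio of 2.53. The list median of 2.12 [-0.27, 5.12] lay at percentile 100 among matched random lists. VIM, an intermediate filament protein (4.96), and the NODAL inhibitors LEFTY1 (3.86) and LEFTY2 (4.16) were among the highest, while SMAD3 (-1.19) and ACVR1B (-0.59) of the NODAL pathway list were lower, and the list had 2 higher and 2 lower of 7 genes and a median of -0.25 [-1.19, 4.16].

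Genes of epithelial junctions and fluid transport were lower in these cells for 11 of 19 and higher for 0, including JUP, a junction protein also called plakoglobin (-1.63), and DSP, a desmosome protein (-1.17). Their median log2 ratio was -0.68 [-1.07, -0.056], and without CLDN4, which lay at the background level, 10 of 18 were lower. Trophectoderm markers were lower in the same cells for 3 of 6 genes and higher for 1, with a median of -0.75 [-2.11, 1.13], including GATA3 (-2.11), SLC7A2 (-1.57) and KRT19 (-1.30). TET2, an oxidase of 5-methylcytosine, had a log2 ratio of -3.44, and ATP6V0D2 -4.39. Among DNA methylation genes, TET2, DNMT3L (-1.45) and TET3 (-0.78) were lower, and DNMT3B (0.66) and ZFP57 (0.59) were higher, with 7 of 12 within 1.5-fold. Among histone variant genes, H1F0 (-1.61), H2AFY2 (-1.06) and H1FX (-0.88) were lower, and H2AFX (0.96) and H2AFZ (0.75) were higher. The trophectoderm markers in these cells were low relative to the whole library, although KRT18 stood at 492 and 429 CPM. The list's median level, 10.3% and 14.9% of the whole-library level, set the background limit. GATA3, KRT18, KRT19 and SLC7A2 lay at or below that limit in the library with the higher level. For them, expression and RNA from other cells were not separated. ABCG2 (1.13) stood at 33.3% in the library labelled shH2AJ, above the limit. The mitochondrial share of UMIs in this class was 3.19% and 5.75%. Cluster 3, led by C9orf135 and ARGFX, held 1067 of the 1083 cells labelled shControl. Clusters 1, 4 and 8 held 2943, 1033 and 234 of the cells labelled shH2AJ, so these ratios compare different clusters. NODAL, SFRP2, LEFTY1, LEFTY2 and THY1 lead cluster 4 and so also help to set the clusters apart. The primed epiblast median, which is the ratio of CD24 in the main setting, stayed between 2.03 and 2.16 over 11 alternatives. These included clustering without marker genes, where clusters were still named from the same lists.

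The fourth comparison looked within trophoblast-like cells, 2328 cells labelled shControl and 1091 labelled shH2AJ. Trophectoderm markers, which also served to name this class, stayed within 1.5-fold for 13 of 15 genes, with a median log2 ratio of 0.031 [-0.26, 0.20]. HAND1 (1.43 [1.38, 1.476]), a transcription factor, and KRT7 (1.248), a keratin, were higher. Polar or late trophectoderm markers were lower for 4 of 5 genes, including S100P (-1.95), MUC15 (-1.14) and NR2F2 (-0.63). Of 4 measured syncytiotrophoblast genes, CGA, the common subunit of chorionic gonadotropin (-2.06), GCM1, a transcription factor of syncytial fusion (-0.97), and CYP19A1, the aromatase (-0.74), were lower. HSD3B1, a steroid dehydrogenase of the placenta, was higher, at 142 against 21.5 CPM (2.72 [2.62, 2.82]). The highest log2 ratio was that of ANKRD1, a target of YAP signalling, at 22.5 against 0.714 CPM (4.98 [4.51, 5.48]). CCN1, another YAP target, was also higher (1.91), while the 8 measured YAP and TEAD genes had a median of -0.077 [-0.52, 4.98], between -0.115 and 0.50 over 11 alternatives. IGFBP3, a marker on the amnion list, was higher (4.77), while WNT6 (-0.61) and VTCN1 (-0.60) of that list were lower.

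Genes of the unfolded protein and amino acid stress list were lower in these cells for 8 of 17 and higher for 1, with a median log2 ratio of -0.51 [-1.37, -0.061]. They included CHAC1 (-2.46), DDIT4 (-2.06), TRIB3 (-1.95) and PCK2, the mitochondrial phosphoenolpyruvate carboxykinase (-1.69), while HYOU1, a chaperone, was higher (0.94). SLC7A11, a cystine transporter outside that list, had a log2 ratio of -1.80. Cholesterol synthesis genes were lower for 8 of 16 and higher for 1, including SREBF2 (-1.09), the regulator of the pathway, and FDFT1 (-1.04). All 6 measured metallothioneins were higher, with a median of 1.11 [0.834, 1.43], or 0.48 at the finer clustering resolution and 1.67 with each library clustered alone. Of the naive epiblast markers, 5 were higher and 1 lower of 11, with a median of 0.51 [-0.086, 1.51], but -0.37 under the strict cell filter, -0.80 at the finer resolution and 2.25 with each library clustered alone. Their median level, 14.1% and 11.98% of the whole-library level, set the background limit. The 5 higher markers lay at or below it, so expression and RNA from other cells were not separated for them, and 0 of the 3 markers above it were higher. DPPA3, 1 of these 3, was lower (-0.84) and stood at 104.9% and 59.7% of its whole-library level. GRID2 and RASGRF2, both among the 12 highest ratios and in neither list, lay at or below that limit. The mitochondrial share of UMIs in this class was 5.89% and 6.97%. Clusters 2 and 6 held 1526 and 788 of the cells labelled shControl, and cluster 5, led by ANKRD1, HSD3B1 and NPPB, held 1018 of the cells labelled shH2AJ. Cluster 6, led by CGA, PGF, MUC15 and CYP19A1 among others, held 24 cells labelled shH2AJ. Late trophectoderm markers had a mean log2 over other cells of 1.8 in cluster 6, 0.825 in cluster 2 and -0.171 in cluster 5. For syncytiotrophoblast markers these values were 0.712, -0.298 and -0.037. How far the lower markers go with the low number of cluster 6 cells was not tested. Cluster 5 also had amnion markers at a mean log2 of 0.57 over other cells, while between the libraries the amnion list was higher for 2 and lower for 3 of 5 genes in this class, with a median of -0.58. In the same class only 2 of 16 listed hypoblast markers reached 10 CPM in the higher library, APOA2 (4.10) and COL4A1 (1.09), and both were higher.

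**Figure D4:**
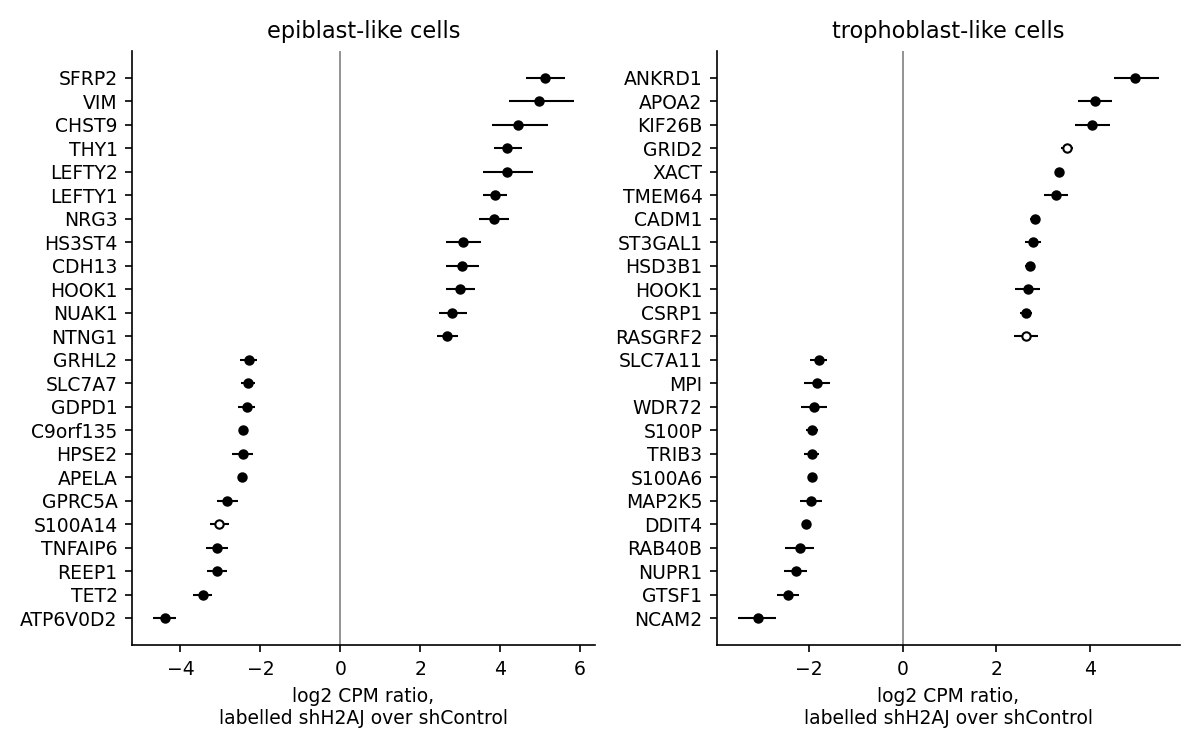
Log2 CPM ratio of the library labelled shH2AJ over the library labelled shControl (horizontal axis) for the 12 highest and 12 lowest genes within epiblast-like cells (left) and trophoblast-like cells (right), with exact 95% counting intervals. Open circles mark genes at the background level, which are S100A14 on the left and GRID2 and RASGRF2 on the right.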

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

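The share ratios at equal depth and over all barcodes are alternatives fixed before the data were examined, and were read as tests after the results were seen, when the other tests in this part were chosen. Several results had opposite directions in the 2 main classes, and none of these differences was tested. Between trophoblast-like and epiblast-like cells, the log2 ratio of the library labelled shH2AJ over the library labelled shControl differed by 0.394 for H2AFJ. It differed by -0.857 for the median of the cholesterol synthesis list, which was 0.35 [0.038, 0.55] in epiblast-like cells and -0.51 [-0.844, 0.087] in trophoblast-like cells, an interval that includes 0. BAMBI, an inhibitor of BMP signalling, was lower in epiblast-like cells (-0.77) and higher in trophoblast-like cells (0.64), a difference of 1.403. DNMT3B, a DNA methyltransferase, had log2 ratios of 0.66 and -0.60, a difference of -1.265. OCLN, a tight junction protein, had log2 ratios of -0.68 and 0.74, a difference of 1.426.

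The first pattern weighed was that H2AFJ was not lower in the library labelled shH2AJ. A lower level hidden by the shares of the 2 main classes is argued against. The lowest log2 ratio within them was -0.231, far from the 1.5-fold limit. Makeup within a class stays open, because the class ratios set different clusters against each other. Within clusters 2, 3 and 6 H2AFJ stood at 24.9, 59.6 and 36.1 CPM in the library labelled shH2AJ against 26.2, 36.6 and 37.1 CPM. These clusters held 49, 67 and 24 cells labelled shH2AJ. H2AFJ was lower in the unnamed clusters 7 (16.3 against 42.55 CPM), 9 (2.7 against 12.4) and 11 (38.75 against 112), but not in clusters 10 and 12. An exchange of the 2 labels stays open, since the whole-library interval, with bounds of -0.087 and 0.082, speaks for neither order. Reads of other H2A genes counted as H2AFJ stay open: 25 other H2A genes together had a log2 ratio of 0.198, and the shared part cannot be told apart from counts. A single wrong label, or an effect on protein that RNA does not show, stays open and untested.

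The next pattern was the lower share of trophoblast-like cells in the library labelled shH2AJ. Depth per cell is argued against as the whole cause, since the share ratio was 0.306 with cells thinned to 4784 UMIs, which left out 336 and 588 shallower cells. Uneven loss of barcodes at the filters is also argued against, with a ratio of 0.38 over all barcodes. With 1 library per genotype, a culture or library batch and the genotype cannot be told apart, and an effect of the hairpin stays open and untested.

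The last pattern was that the libraries stayed apart within a class, with 94.5% and 98.1% of neighbours from the same library for epiblast-like and trophoblast-like cells labelled shControl, against 20.2% and 68.1% if mixed. Depth is argued against, since at equal depth the lower of the ratios to mixed libraries, taken for the smaller library of each class, was 2.81. RNA from other cells stays open as a part of it, since no value here separates it from expression across genes. A batch, with 1 library per genotype, and the genotype cannot be told apart here either.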

How the results depend on the processing

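The cause of the shifts below was not tested. At resolution 1.0, 45.0% of cells labelled shControl went unnamed. The log2 ratio of H2AFJ over all cells was -0.117 with every cell weighing the same and -0.134 with median-of-ratios scaling, and stayed within 1.5-fold throughout. The trophoblast-like share ratio was 0.38 over all barcodes, 0.262 under the strict filter, 0.584 at resolution 1.0 and 0.399 with each library clustered alone, below 1 in 11 of 11 alternatives. The epiblast-like ratio was 3.212 over all barcodes, 2.847 at resolution 1.0, 1.936 with each library alone and 2.9 at equal depth. The hypoblast-like ratio was 14.372 under the strict filter, 1.016 by marker score and, reversed, 0.243 with each library alone. With both libraries weighted to the same class shares, the whole-library medians were 0.08 for naive epiblast and -0.008 for trophectoderm markers, lists that also named the classes. JUN reversed, from a log2 ratio of 1.08 to -0.074 when every cell weighed the same. Ratios of single genes were recomputed only under the cell filters, without doublet removal and under the other scalings. They were not recomputed under the clustering, naming, equal-depth or class-weight alternatives. Of these 2316 values for 386 genes, 1994 stayed within their counting interval, 321 moved outside it and 1 reversed. Under these alternatives 18 of 326 genes past the 1.5-fold rule came under it at least once. Of 553 values for 55 lists, 543 stayed within their interval and 10 moved. Added after the data were seen, counting the late trophectoderm cluster as trophoblast-like gave a ratio of 0.308, and shares of named cells alone gave 0.296. No paired analysis was possible because each genotype has 1 library. With 13 and 60 hypoblast-like cells, counting error alone left their share ratio between 1.64 and 5.995.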

Other observations

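CSH1, a placental lactogen gene, was found in epiblast-like cells of the library labelled shH2AJ, at 15.4 CPM from 683 UMIs against 2 UMIs in the library labelled shControl, a log2 ratio of 7.20 [5.35, 10.25]. At least 1 CSH1 UMI was found in 301 of 2943 cells of cluster 1 and 108 of 1033 cells of cluster 4, both epiblast-like, against 21 of 1018 cells of the trophoblast-like cluster 5 of the same library, where the CSH1 level of the class (1.45 CPM, 13.2% of the whole-library level) is read as background. The median depths of these clusters were 9794, 8346 and 15240.5 UMIs. Reads of CSH1 can be shared with its near-identical neighbour CSH2, so the assignment to CSH1 is uncertain. LDHA, a lactate dehydrogenase subunit, was higher in the library labelled shH2AJ in both classes, at 685 against 175 CPM in epiblast-like cells and 1037 against 406 CPM in trophoblast-like cells. LDHA was also higher within cluster 2, at 595 against 348 CPM. Within cluster 3 it stood at 255 against 174 CPM, a difference under the 1.5-fold rule. H1F0, a linker histone, had log2 ratios of -1.61 and -0.49 in the 2 classes, which set different clusters against each other. Within cluster 3 H1F0 stood at 180 CPM in the library labelled shH2AJ against 131 CPM, and within cluster 2 at 70.6 against 72.2 CPM. These clusters held only 67 and 49 cells labelled shH2AJ. The median mitochondrial share in cluster 3 was 0.2% against 2.85%. In the unnamed cluster 7, with 294 and 251 cells, H1F0 was lower, at 34.2 against 141 CPM. It was also lower in clusters 5, 9, 10 and 11, and within 1.5-fold in clusters 6 and 12, each with few cells or UMIs in 1 library. Clusters 5, 11 and 12 held 14, 17 and 13 cells labelled shControl, and cluster 6 held 24 cells labelled shH2AJ. In the library labelled shH2AJ, H1F0 had 10 UMIs in cluster 9 and 3 in cluster 10. Genes of the G2 and M phases were higher for 10 and lower for 1 of 47 in epiblast-like cells, and higher for 11 and lower for 2 of 47 in trophoblast-like cells, with medians of 0.26 [0.14, 0.45] and 0.31 [0.19, 0.43]. Genes of the S phase were higher for 3 and lower for 3 of 36 in epiblast-like cells, and higher for 6 and lower for 2 of 36 in trophoblast-like cells.

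The unnamed cluster 11, led by the interferon-induced genes DDX60, IFIT2 and IFIT1, held 17 cells labelled shControl and 66 labelled shH2AJ. Cluster 8, within the epiblast-like class and led by H3.Y and CCNA1, held 2 and 234 cells, and its mean log2 level of eight-cell markers over other cells was 0.78. KHDC1L, the 1 eight-cell marker measured in epiblast-like cells, was lower there (-0.93), and stood at 1083 CPM in cluster 8 against 2019 CPM in cells of cluster 3 labelled shControl. Across 6020 genes, the log2 ratios within the 2 classes had a Pearson correlation of 0.68 and a Spearman correlation of 0.67, where genes are not independent replicates and both ratios come from the same pair of libraries.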
